A study of Rattus norvegicus with 4 samples.

How the data were processed

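RNA was sequenced from primary cultures of neonatal rat ventricular myocytes, the contractile cells isolated from Sprague-Dawley rat hearts at neonatal day 1 to 2. Per the labels' protocols, cells were isolated and cultured in medium with 10% serum and then kept for 5 days after infection in medium with 2% serum. The 4 groups were an untreated control, cells infected with an adenovirus carrying CryAB R120G, and infected cells that also received either siUbe2v1 or an adenovirus carrying Ube2v1. Each group was cultured in triplicate, and per the series design text and the labels' protocols the total RNA of a group was pooled before a stranded poly(A) mRNA library was made. Each group is therefore 1 library of RNA pooled from 3 cultures. No spread between cultures can be computed, no test across samples was possible, and no p-value, SD between cultures or standard error is given.

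The deposited table gives 1 FPKM value per gene symbol and library (fragments per kilobase of transcript, scaled to the mapped fragments of the library). The submitters' processing notes name cutadapt, TopHat and Cufflinks as tools, without versions or parameters. The genome build and the annotation are not given in the sources used here, so no coordinates are printed. The table held 28570 gene rows, and 10057 of them were at 0 in every library. Zeros in this table can be failed estimates: Hsp90aa1, Capns1, Map3k7 and Rplp2, which most cells use, were listed at 0 in every library. Values above 0 can be misassigned too, and Chd9, which ranged from 4.33 to 960 FPKM, is printed with that doubt open. Genes listed at 0 in 1 library of a comparison are given no fold change here.

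FPKM values alone do not give the number of reads, and the absolute depth is unknown. The relative depth of the libraries was read from the steps of low values. Among genes below 0.3 FPKM in every library, the ratio of a gene's values in a pair of libraries peaks where both hold the same number of reads. The peaks placed the depth at 1.06 times that of the control library for R120G, 1.09 times for R120G with siUbe2v1 and 1.34 times for R120G with AdUbe2v1. Between 10.85% and 19.3% of these genes lay within 0.03 on the log2 scale of the peak. Because reads per gene were not recovered, no counting interval is given, and low values are less precise than high ones to an unknown degree.

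All computations were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Genes with a mean of at least 1 FPKM over the 4 libraries were kept, which left 11841. Each comparison is a log2 ratio of (FPKM + 1) in one library to (FPKM + 1) in the other, a scale that understates the change of low genes. In place of a test, a fixed rule of size was used: a gene counts as higher or lower at a log2 ratio of at least 1 or at most -1, that is, 2-fold. Gene symbols were matched to the symbols and synonyms of a RefSeq rat gene table of assembly GRCr8 for names and gene types only. Of the 28570 symbols, 19222 (67.3%) matched, and 10867 of the tested genes were protein coding.

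Before the data were examined, 28 gene lists (pathways, cell types and quality signs), the rule of size, the filter, the pseudocount, the other settings and the rule for named genes were fixed. The ribosomal protein and immediate early lists were among the quality signs. Of the 780 list entries, 662 were tested, 68 had a mean below 1 FPKM, 33 were not matched under the listed symbol and 17 were listed at 0 in every library. A list with at least 5 tested members was described by its median log2 ratio. This median was set beside the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is called outside the random range when its median lay below the 2.5 or above the 97.5 percentile. This places the list within the pair of libraries compared and says nothing about how cultures vary. The erythroid and the Schwann and neural lists had too few tested members, and 26 lists remained.

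The rule for named genes took Ube2v1, Ube2v2, Ube2n, Cryab, Nppa, Nppb, Myh6 and Myh7 in every comparison, and per comparison the 8 highest and 8 lowest genes with an assigned name and a mean of at least 5 FPKM. It also took up to 4 members of each list outside the random range, the 2 most abundant tested members of each cell type list, and up to 5 genes on each side of the set that moved in opposite directions. As written, the rule filled the 8 highest and 8 lowest places with small noncoding RNA genes that were listed at 0 in 1 of the libraries. The 8 highest and 8 lowest protein-coding genes above 0 in both libraries are therefore named instead, a choice made after the values were seen. Examples of lists that were not outside the random range, and members past 2-fold against the direction of their list, were also chosen after their values were seen. Some genes that the rule selects are not reported here.

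The procedure was tested on simulated data made from the means of the 11841 tested genes, with noise drawn from the ratios of the AdUbe2v1 and siUbe2v1 libraries. In a simulated R120G and control comparison, 98% of 100 genes changed 3-fold and 3% of 100 genes changed 1.5-fold passed the 2-fold rule, as did 2.24% of unchanged genes. The changed genes had a mean above 5 FPKM, lay outside every list and were shifted on the scale of FPKM + 1. The 98% and 3% therefore do not hold for lower genes, which the 2.24% includes. A list shifted by 0.5 was recovered at 0.52 and outside the random range, and 0 of 25 other lists were outside it. The noise was drawn for each gene independently. The simulation therefore cannot show how often a list whose genes move together falls outside the range without an effect. For the pair of comparisons that share the R120G library, 100 simulations of unchanged libraries drew noise of the same size for every library. They gave the values due to sharing when no library deviates more than another, a setting that fixes the correlation near 0.50. The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, scaling to the same total, scaling by the median ratio, a 1.5-fold rule and 10 bins. Chosen after seeing the data were an alternative with protein-coding genes only and another with the control library in place of R120G.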

Results

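The effect of the E2 variant protein Ube2v1 on the transcriptome of stressed heart muscle cells was addressed by RNA sequencing of neonatal rat ventricular myocytes. CryAB R120G is a mutant of the small heat shock protein alpha B-crystallin that aggregates and causes a desmin-related cardiomyopathy. Ube2v1 acts with Ube2n to build ubiquitin chains linked through lysine 63. The data comprised 4 libraries, 1 per group, each made from RNA pooled from 3 cultures: an untreated control, R120G, R120G with siUbe2v1 and R120G with AdUbe2v1. The control received no virus, so the comparison with R120G includes infection itself. No library with a control siRNA or a control virus was used, so the ratios over R120G include the added reagent itself. The libraries had 16435 (control), 16534 (R120G), 16526 (siUbe2v1) and 17120 (AdUbe2v1) genes above 0 FPKM. Mitochondrially encoded transcripts made up 13.8%, 17.01%, 19.6% and 17.5% of total FPKM in the same order. Small noncoding RNA genes made up 9.34%, 1.52%, 7.51% and 8.19%, so the R120G library stood apart in that share. Single genes carried much of it: SNORD45 was at 29037 FPKM and SNORD24 at 9497 FPKM in control, and both were listed at 0 in R120G. The share therefore rests on estimates that can fail, and the totals used for scaling include these genes. Genes known by an identifier only made up 16.2%, 3.64%, 4.19% and 9.84%, highest in the control library. Protein-coding genes summed to 386506, 448421, 389245 and 388288 FPKM, highest in the R120G library.

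Cryab, the gene of the overexpressed protein, was at 837 FPKM in the control library and at 1585, 1565 and 1533 FPKM in the R120G, siUbe2v1 and AdUbe2v1 libraries. Its log2 ratio was 0.92 for R120G over control, and -0.02 and -0.05 for the siUbe2v1 and AdUbe2v1 libraries over R120G. Scaled to the same total, the first of these was 1.08. These values hold reads of the endogenous gene together with whatever transgene reads aligned to it. Ube2v1 itself was not analysed here, so neither knockdown nor overexpression was checked in these values. Tmem189, a synonym of the neighbouring gene Peds1, was at 40.2, 47.5, 38.7 and 37.4 FPKM in control, R120G, siUbe2v1 and AdUbe2v1, and whether its row also holds Ube2v1 reads is not known. Its partner Ube2n was at 40.2, 42.8, 46.6 and 44.9 FPKM in control, R120G, siUbe2v1 and AdUbe2v1. The paralog Ube2v2 was at 17.9, 23.1, 23.5 and 21.7 FPKM. As a family of lysine 63 chain enzymes and regulators, the list of 24 tested genes stayed inside the random range in all 4 comparisons, and none of its members differed 2-fold in any of them.

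The first comparison asked what differed in cells carrying R120G. Mitochondrial respiration and fatty acid genes stood higher in the R120G library, and inflammatory, immediate early and smooth muscle genes stood lower. The sum of FPKM over protein-coding genes was also higher there, at 448421 against 386506. Of 37 nuclear genes of oxidative phosphorylation, all 37 were above the control library, 4 of them 2-fold. Their median log2 ratio was 0.80, where the central 95% of matched random lists ran from 0.13 to 0.42. Cox8b, a muscle isoform of a cytochrome c oxidase subunit, went from 139 to 380 FPKM (log2 ratio 1.45), and the complex I subunits Ndufs3 and Ndufv1 had log2 ratios of 1.03 and 1.03. Uqcrq of complex III had 1.04. Genes of fatty acid uptake and oxidation had a median of 0.64 over 28 genes (random range -0.05 to 0.33), with 5 at 2-fold higher and none lower. They included Hadh at 43.4 FPKM against 16.6 in control, Decr1 (1.11), Ech1 (1.09) and Ucp2 (1.05). The 26S proteasome list had a median of 0.45 (random range 0.03 to 0.41). All 31 of its subunits were above the control value but none reached 2-fold, and Psmc3 had the largest ratio, 0.73, followed by Psmb5 (0.65), Psmc5 (0.64) and Psmb6 (0.64).

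Lower in the R120G library were 12 of 25 NF-kB and inflammatory genes at 1.5-fold, 7 of them at 2-fold, with a median of -0.56 (random range -0.15 to 0.26). The prostaglandin synthase Ptgs2 had a log2 ratio of -1.93, the receptor Il1rl1 -1.90, the iron-binding protein Lcn2 -1.68, and the chemokine Ccl2 -1.67 (393 to 122 FPKM). Immediate early genes, a list fixed as a quality sign, had a median of -0.54, with Fos at -1.17, Dusp1 at -1.19, Nr4a3 at -1.34 and Klf6 at -1.07. Fetal and hypertrophy genes had a median of -0.51 over 21 genes (random range 0.00 to 0.44), and 5 were 2-fold lower and none higher. Xirp2, an actin-binding protein of the intercalated disc, was at -1.74, Ctgf at -1.52, Bdnf at -1.34 and the calcineurin regulator Rcan1 at -1.24. The natriuretic peptide genes did not reach 2-fold: Nppa went from 10399 to 6190 FPKM (-0.75) and Nppb had a ratio of -0.60. Interferon-stimulated genes had a median of -0.25 (random range -0.17 to 0.18), and Cxcl10 (-1.87), Ifit3 (-1.60), Oasl (-1.51) and Isg15 (-1.33) were among 6 at 2-fold lower. In R120G these named genes were low, at 1.36, 0.51, 0.80 and 3.43 FPKM in the same order. Integrated stress response targets (median -0.25) included Atf3 (-1.74), Ddit4 (-1.46), Vldlr (-0.67) and Ppp1r15a (-0.50). Cholesterol synthesis genes (-0.27) had none at 2-fold, and they included Hsd17b7 at -0.92, Sc5d at -0.84 and Lss at -0.72. Glycolysis genes (median -0.14, mean -0.01) went both ways: Pgam2 (2.38), Eno3 (1.39) and Ldhb (1.31) were 2-fold higher and Hk2 (-1.55) and Pfkl (-1.07) 2-fold lower, with Pdk1 at -0.81 and Pfkfb2 at -0.59. Cell cycle genes had a median of -0.19, which was inside the random range under a mean of at least 5 FPKM (-0.09), and none at 2-fold: Cenpe was at -0.85, Mki67 at -0.66, Ccnb1 at -0.66 and Top2a at -0.58.

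Cell type markers moved as well between these libraries. Smooth muscle and pericyte markers had a median of -0.57 (random range -0.11 to 0.39), with Rgs5 at -1.56, Cspg4 at -1.06, Notch3 at -0.93, Myh11 at -0.91, Tagln at -0.63 and Acta2 at -0.06. Fibroblast and matrix markers had a median of -0.23 (random range 0.05 to 0.41) but went both ways, with 13 above and 17 below control. In that list 6 were 2-fold lower, among them Lox (-1.59), Col6a3 (-1.48), Ddr2 (-1.33) and Fbln2 (-1.25), and 1 was 2-fold higher, Ogn (1.22), while the abundant Col3a1 was at 0.12 and Col1a1 at -0.41. Macrophage and leukocyte markers stood higher, with a median of 0.38 (random range -0.21 to 0.25): Adgre1 was at 1.75, Aif1 at 1.08, Cd68 at 0.73, Trem2 at 0.62, Fcer1g at 0.61 and Lyz2 at 0.04. Chaperones (median 0.16), endoplasmic reticulum chaperones (0.10), autophagy and lysosome genes (0.28), NRF2 targets (0.27), immunoproteasome genes (0.28), p53 targets (0.07) and ribosomal proteins (0.35) were inside the random range. Sarcomere genes had a median of 0.40, inside the random range, although 5 of 27 were 2-fold higher. Tnnt2 went from 1786 to 3969 FPKM (1.15), while Actc1 (0.40), Myh6 (0.72) and Myh7 (-0.45) stayed under 2-fold. The 2 most abundant tested endothelial markers, Eng and Kdr, were at -0.30 and 0.01, the epicardial markers Aldh1a2 and Krt18 at 1.32 and 0.36, and the neural markers Tubb3 and Cnp at 0.15 and 0.17. The epicardial list as a whole had a median of -0.12, inside the random range, with 5 above and 6 below control.

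Over all tested genes, 282 were 2-fold higher and 366 were 2-fold lower in the R120G library. Scaling the libraries to the same total FPKM turned that split to 467 higher and 253 lower, and scaling by the median ratio gave 240 and 410. Of the 648 genes, 79 were listed at 0 in 1 of the libraries, and protein-coding genes alone gave 210 higher and 283 lower. The 8 highest protein-coding genes were Reg3b, a secreted lectin (48.1 to 343 FPKM, log2 ratio 2.81), the thioredoxin-interacting protein Txnip (38.0 to 269 FPKM, 2.79), Cited1 (2.54), the muscle phosphoglycerate mutase Pgam2 (2.38), Cited4 (2.29), Arrdc4 (2.29), Atp6ap1l (2.18) and the growth factor Ptn (2.14). The 8 lowest were Chd9 (-7.49, from 960 to 4.33 FPKM, values whose spread leaves open a failed or misassigned estimate, here and in the ratios over R120G), Esm1 (-2.28), the activin subunit Inhba (-2.28), Abra (-2.22), Ndufa4l2 (-2.15), Syne2 (-2.12), Zbtb20 (-2.09) and Gem (-2.06). With 1 pooled library per group, these ratios have no replicate check. The median over all tested genes was 0.05 and moved to 0.18 under scaling to the same total, against which the list values are to be read.

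**Figure D1:**
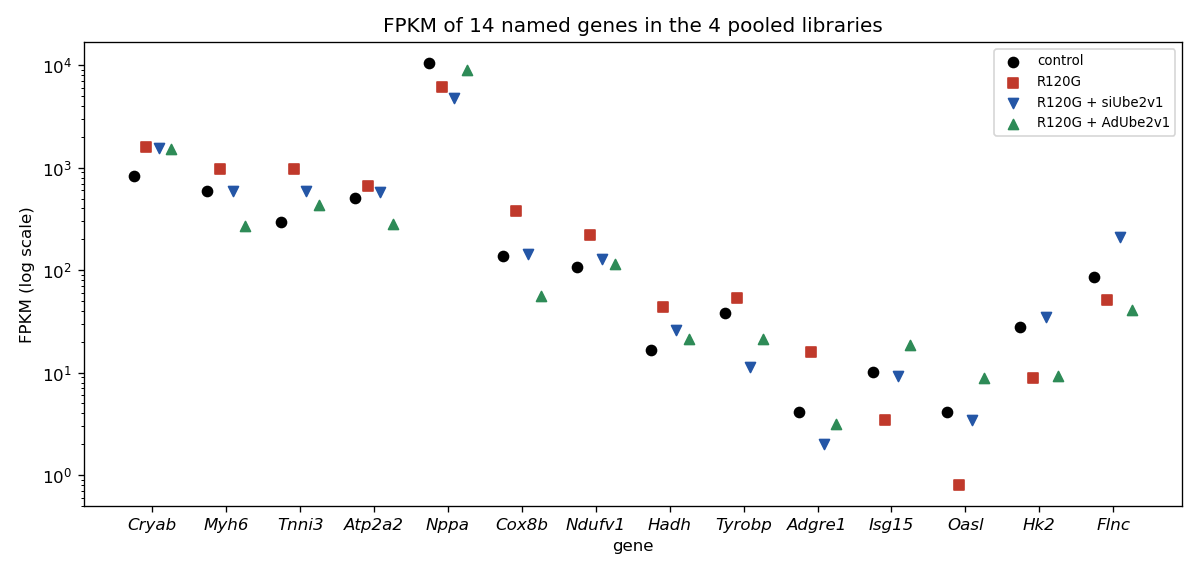
FPKM on a log axis of 14 named genes in the control, R120G, R120G with siUbe2v1 and R120G with AdUbe2v1 libraries; each point is 1 pooled library and there are no error bars because no replicates exist. Cryab was at 1585, 1565 and 1533 FPKM in the infected libraries against 837 in control, Tyrobp and Adgre1 were lowest with siUbe2v1, and Myh6 was lowest with AdUbe2v1.

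The second comparison asked what differed when siUbe2v1 was added to R120G cells. Macrophage and leukocyte markers stood apart most: all 19 tested were below the R120G library, 14 of them 2-fold, with a median of -1.34 (random range -0.31 to 0.13). Adgre1 went from 16.0 to 2.00 FPKM (-2.51), Aif1 from 17.7 to 3.10 FPKM (-2.19), Tyrobp from 53.2 to 11.4 FPKM (-2.13), Fcer1g from 60.9 to 15.3 FPKM (-1.92) and Lyz2 from 178 to 58.9 FPKM (-1.58). Interferon-stimulated genes had a median of 0.59 over 37 genes (random range -0.23 to 0.08), with 11 at 2-fold higher and none lower. They included the transcription factor Irf7 (5.56 to 20.1 FPKM, 1.68), Cxcl10 (1.36 to 6.54 FPKM, 1.68), the viral tethering factor Bst2 (1.31) and Oasl (0.80 to 3.46 FPKM, 1.31). Fetal and hypertrophy genes had a median of 0.53 (random range -0.39 to -0.01) and 5 members at 2-fold higher, with Xirp2 at 1.81, Hbegf at 1.34, Rcan1 at 1.16 and skeletal actin Acta1 at 1.08. The natriuretic peptide gene Nppa was at -0.36 and Nppb at 0.37. Against the control library, fetal and hypertrophy genes with siUbe2v1 had a median of 0.07, inside the random range (-0.09 to 0.17). The R120G library had -0.51 against control, so the ratio over R120G also holds the low values of that library.

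Oxidative phosphorylation genes stood lower with siUbe2v1, with a median of -0.52 (random range -0.36 to -0.10). All 37 were below R120G but only Cox8b (-1.38) reached 2-fold; Ndufv1 was at -0.78, Cox4i1 at -0.76 and Ndufb10 at -0.74. Fatty acid genes also had a median of -0.52 (random range -0.31 to 0.01), and 27 of 28 were below R120G. Pdk4, which restrains pyruvate oxidation, was at -1.15 and the only one at 2-fold, and Ech1, Cpt1b and Eci1 were at -0.83, -0.81 and -0.79. Ribosomal protein genes had a median of -0.39, at the edge of the random range (-0.38 to -0.10), with Rps15 at -0.61, Rpl18 at -0.55, Rps27 at -0.54 and Rpl35 at -0.53. Under a mean of at least 5 FPKM the ribosomal list was inside its random range. The 26S proteasome list had a median of -0.29, inside the random range, with 29 of 31 subunits below R120G. Autophagy and lysosome genes had a median of -0.31, at the edge of the range and outside it with no filter, by the median ratio, with 10 bins and with protein-coding genes only, with 34 of 36 below R120G.

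Higher with siUbe2v1 were cell cycle genes, with a median of 0.28 (random range -0.23 to 0.07) and 34 of 38 members above R120G, none at 2-fold. Top2a was at 0.78, Rrm2 at 0.70, Ccnb1 at 0.69 and Bub1 at 0.67. Immediate early genes, the same quality list, had a median of 0.20, with Fosb at 1.74, Nr4a3 at 1.17, Fosl1 at 1.01 and Nr4a1 at 0.77. Of these, Fosb (0.36 to 3.55 FPKM), Nr4a3 (0.67 to 2.75 FPKM) and Fosl1 (1.73 to 4.49 FPKM) were low. Glycolysis genes went both ways, with 14 above and 10 below R120G, a mean of 0.00 and a median of 0.04 against a random range of -0.36 to -0.01. Pgam2 (-1.14) and Eno3 (-1.04) were 2-fold lower. Hexokinase 2 (Hk2) went from 8.83 to 34.6 FPKM (1.86), and Slc2a1, Slc16a3 and Pfkfb3 were at 0.80, 0.61 and 0.41. Fibroblast and matrix markers had a median of 0.29 (random range -0.36 to -0.06), with Fn1 at 360 FPKM in R120G and 773 with siUbe2v1, and ratios for Tnc of 1.07, Ddr2 of 0.91, Dcn of 0.78, Col1a1 of 0.23 and Col3a1 of 0.06. Smooth muscle and pericyte markers had a median of 0.09, with Cspg4 at 1.37, Cnn1 at 0.94, Abcc9 at 0.73, Synpo2 at 0.59, Acta2 at 0.02 and Tagln at -0.04. Endothelial markers, only 8 of which were tested, had a median of -0.46 (random range -0.38 to 0.26), with Ecscr at -0.72, Icam2 at -0.55, Esam at -0.50, Kdr at -0.46 and Eng at -0.45. All of these but Eng were low, at 1.81, 2.18, 1.87 and 3.88 FPKM in R120G. Sarcomere genes stayed inside the random range, with Myh6 at -0.70, Tnnt2 at -0.64, Myh7 at -0.08 and Actc1 at 0.10. The epicardial markers Aldh1a2 and Krt18 were at -1.08 and -0.68, and Tubb3 and Cnp at 0.14 and -0.10. The epicardial list as a whole had a median of 0.13, inside the random range, with 6 above and 5 below R120G.

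Over all tested genes, 192 were 2-fold higher and 203 were 2-fold lower with siUbe2v1, and scaling by the median ratio gave 256 and 156. Protein-coding genes gave 130 and 144. The 8 highest protein-coding genes were Chd9 (4.99), the gamma-glutamyltransferase Ggt5 (1.79 to 20.3 FPKM, 2.93), Lcn2 (2.26), Lmcd1 (2.01), filamin C (Flnc, 51.3 to 209 FPKM, 2.01), the deubiquitinase Otud1 (1.86), Hk2 (1.86) and Gbp1 (1.83). The 8 lowest were Adgre1, Aif1, Tyrobp, the M-line protein gene Myom2 (138 to 34.2 FPKM, -1.99), Intu (-1.98, and -0.88 with a pseudocount of 5), Fcer1g, Gngt2 (-1.85) and Mex3a (-1.84). The median over all tested genes was -0.11, and scaling by the median ratio moved it to 0.00. Against the control library in place of R120G, 342 genes were at 2-fold.

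The third comparison asked what differed when AdUbe2v1 was added to R120G cells. Contractile and calcium-handling genes stood lower, and whether the share of myocytes differed between these libraries was not tested. Against the control library, sarcomere genes with AdUbe2v1 had a median of -0.10 (random range -0.04 to 0.18), with 11 above and 16 below. Over R120G, sarcomere genes had a median of -0.68 over 27 genes (random range -0.36 to -0.05), with 15 at 1.5-fold lower and none higher. Myh6, the fast ventricular myosin heavy chain, went from 965 to 269 FPKM (-1.84). Myom2 was at -1.69, troponin I (Tnni3) at -1.17 (966 to 428 FPKM) and Myl7 at -1.12, while Tnnt2 (-0.68), Actc1 (-0.49) and Myh7 (-0.36) stayed under 2-fold. Calcium handling and ion channel genes had a median of -0.35 (random range -0.23 to 0.12). The sarcoplasmic reticulum pump Atp2a2 went from 660 to 279 FPKM (-1.24), the histidine-rich calcium-binding protein Hrc was at -1.53, the potassium channel Kcnj11 at -1.37 and Jph2 at -0.68. All 37 oxidative phosphorylation genes were below R120G, with a median of -0.68 (random range -0.35 to -0.09), and 27 of them passed 1.5-fold. Cox8b went from 380 to 56.0 FPKM (-2.74), and Atp5g1, Ndufb10 and Ndufv1 were at -0.96, -0.95 and -0.94. All 28 fatty acid genes were below R120G too, with a median of -0.52, Pdk4 at -1.04, Hadh at -0.98, Ech1 at -0.86 and Acads at -0.84.

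Interferon-stimulated genes had the highest median with AdUbe2v1, 0.76 (random range -0.13 to 0.19), with 27 of 37 at 1.5-fold higher and none lower. Oasl was at 2.45 (0.80 to 8.82 FPKM), Cxcl10 at 2.24 (1.36 to 10.2 FPKM), Isg15 at 2.16 (3.43 to 18.7 FPKM) and Ifit3 at 1.85 (0.51 to 4.42 FPKM). p53 targets and apoptosis regulators had a median of 0.35 (random range -0.20 to 0.15) and went both ways, with 16 above and 10 below R120G; those 2-fold higher were the death receptor Eda2r (1.56), Pmaip1 (1.21) and Tp53inp1 (1.05), and Zmat3 was at 0.99. Integrated stress response targets had a median of 0.27 and none at 2-fold: Gdf15 was at 0.73, Slc7a11 at 0.71, Asns at 0.63 and Trib3 at 0.57. Cholesterol synthesis genes also had a median of 0.27, with 21 of 22 above R120G, Idi1 at 0.85, Stard4 at 0.74, Hmgcs1 at 0.60 and Sc5d at 0.58. Fetal and hypertrophy genes had a median of 0.12 (random range -0.35 to 0.01) but went both ways, with 13 above and 8 below R120G. Tnni1 was 2-fold lower (-1.08) and Xirp2 2-fold higher (1.03), with Bdnf at 0.99, Timp1 at 0.81 and Uchl1 at 0.79, while Nppa was at 0.53 and Nppb at -0.04. Fibroblast and matrix markers had a median of 0.15 (random range -0.32 to -0.02) and also went both ways, with 18 above and 12 below R120G. Dpt was 2-fold lower (-1.18) and Fn1 2-fold higher (1.02), with Fbln2 at 0.98, Lox at 0.96, Col6a3 at 0.92, Col1a1 at 0.23 and Col3a1 at -0.26. Macrophage and leukocyte markers had a median of -0.86, with all 19 below R120G: Adgre1 was at -2.03, Aif1 at -1.85, Fcer1g at -1.47, Tyrobp at -1.28 and Lyz2 at -0.67. Acta2 and Tagln were at -0.45 and 0.23, Eng and Kdr at -0.37 and 0.18, Aldh1a2 and Krt18 at -1.16 and 0.76, and Tubb3 and Cnp at 0.02 and 0.47.

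In this comparison 236 genes were 2-fold higher and 198 were 2-fold lower, and scaling to the same total turned the split to 211 and 233. Of the 434 genes, 87 were listed at 0 in 1 library, and protein-coding genes alone gave 142 and 135. The 8 highest protein-coding genes were Chd9 (5.77), Cxcl10, Isg15, Prrg4 (1.91), Lpp (1.88), Wisp1 (1.69), Inhba (1.65) and the enkephalin precursor Penk (1.63). The 8 lowest were Cox8b, Pgam2 (-2.23), Ptn (263 to 58.1 FPKM, -2.16), Cited1 (-2.14), Atp6ap1l (-2.11), Adgre1, Apoe (277 to 67.6 FPKM, -2.02) and Adamtsl2 (-1.99). Pgam2, Ptn, Cited1 and Atp6ap1l were also among the 8 highest in R120G over control. The R120G library is in both ratios, so a value that was high there by chance would appear in both. Against the control library in place of R120G, 353 genes were at 2-fold.

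**Figure D2:**
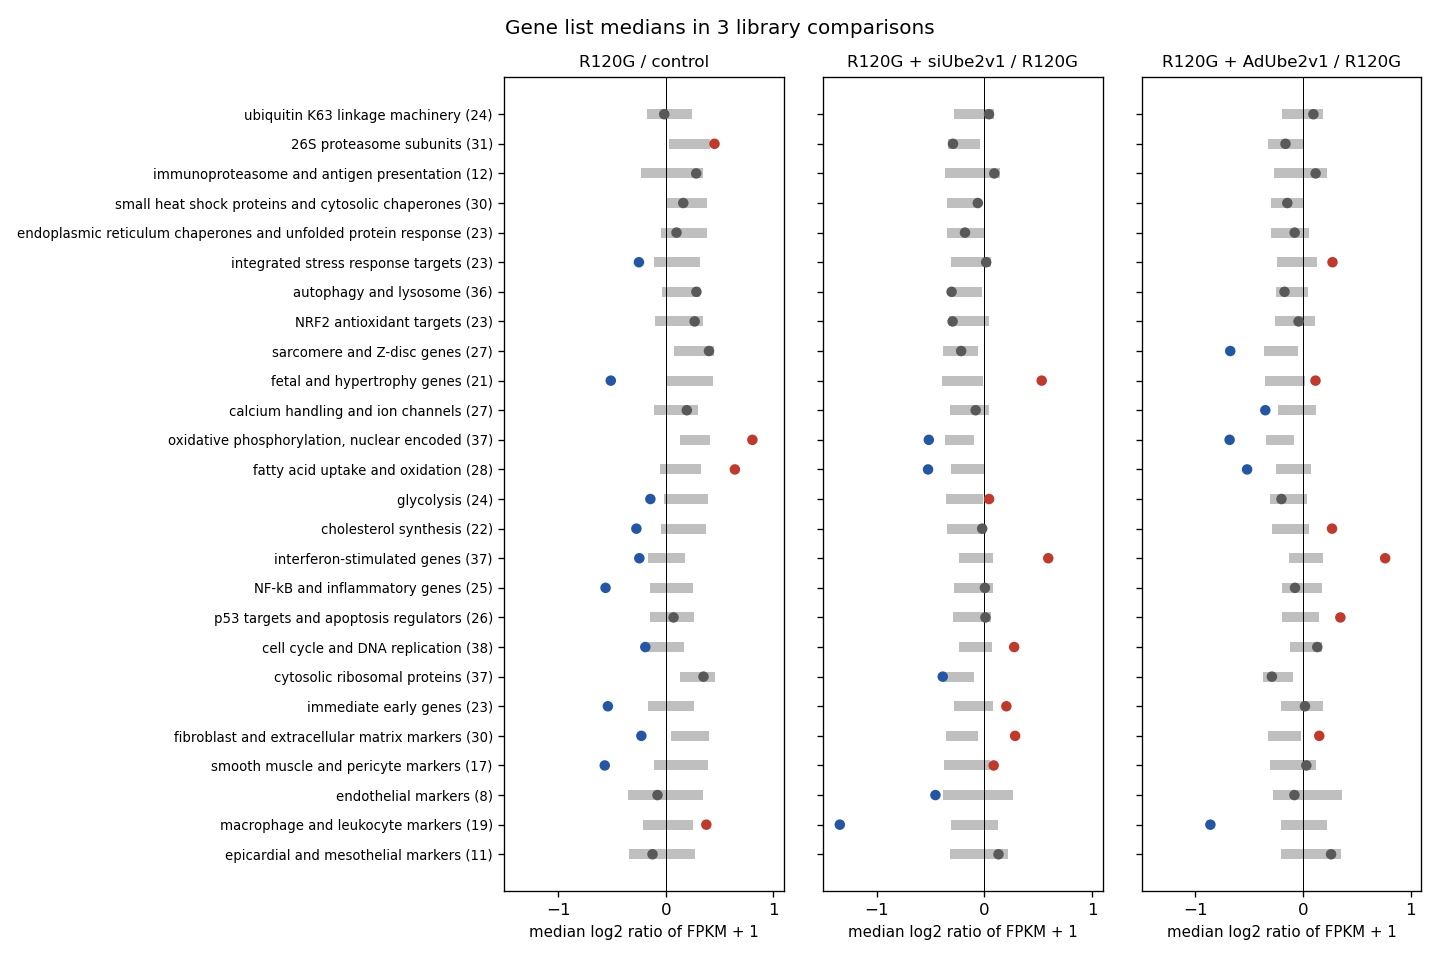
Median log2 ratio of FPKM + 1 (x axis) for 26 gene lists (rows, number of tested genes in brackets) in 3 library comparisons; grey bars are the central 95% of medians of 10000 random lists matched on expression, and red and blue points lie above and below the random range. Oxidative phosphorylation genes had medians of 0.80, -0.52 and -0.68 from left to right, and macrophage markers of 0.38, -1.34 and -0.86.

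Knockdown and overexpression are opposite manipulations of 1 gene, and the next comparison asked which genes moved in opposite directions from R120G. Only 5 of 11841 genes did so at 2-fold, where independent lists of the same sizes would give 7.26 and simulated unchanged libraries sharing R120G gave 2.35. Intu, a planar cell polarity effector, was the 1 protein-coding gene among them: it was at 5.27 FPKM in R120G, 0.585 with siUbe2v1 and 13.4 with AdUbe2v1. With a pseudocount of 5 the siUbe2v1 ratio of Intu was -0.88, under 2-fold, and the number of genes in opposite directions was 3. The others were AABR07070185.1 (67.7, 176 and 31.0 FPKM in the same order), 5S_rRNA (1348, 624 and 3472 FPKM), and SNORA1 and SNORA81, which were listed at 0 with siUbe2v1. In the same direction, 90 genes were higher and 107 were lower in both, where independent lists would give 3.83 and 3.39 and the simulated sharing gave 118 in total. The ratios correlated across genes at Pearson's r = 0.58 (Spearman's rho = 0.81). Simulated sharing gave r = 0.50, a value set by the equal noise of its libraries. Their covariance was 0.27 against 0.19 in the simulation. Among protein-coding genes, 60 were higher and 72 were lower in both, where simulated sharing gave 24.6 in total; r was 0.81 against 0.50 simulated, and the covariance was 0.14 against 0.03. Genes are not independent replicates. The simulation gave all libraries equal noise, but over protein-coding genes the ratios to R120G spread more widely than AdUbe2v1 over siUbe2v1. Their SDs over genes were 0.42 (siUbe2v1) and 0.42 (AdUbe2v1), against 0.26. An R120G library that deviates more than the others would raise r, the covariance and the counts, so all the excess may come from it. A response common to both added reagents would raise them as well, and these causes cannot be told apart.

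The AdUbe2v1 and siUbe2v1 libraries were compared directly, without R120G. Fewer genes differed: 92 were 2-fold higher and 109 were 2-fold lower with AdUbe2v1, and among protein-coding genes 22 and 59. Of the higher genes 51, and of the lower genes 34, were listed at 0 in 1 of the libraries. The total was 1.70% of tested genes, where 2.24% of unchanged genes passed in the simulation. That simulation took its noise from this same pair, so it cannot tell these differences from noise. Sarcomere genes stood lower with AdUbe2v1 (median -0.41, random range -0.06 to 0.09), 26 of 27 being below siUbe2v1, with Myh6 at -1.14, Synpo2l at -0.89, Myl7 at -0.84 and Myom1 at -0.82. Fetal and hypertrophy genes were at -0.42, with Xirp1 at -1.11, Acta1 at -1.05, Rcan1 at -1.04 and Hbegf at 39.7 FPKM with siUbe2v1 and 19.4 with AdUbe2v1. Gdf15 of that list was 2-fold higher, at 30.6 FPKM with siUbe2v1 and 66.8 with AdUbe2v1, and Nppa was at 0.90. Calcium handling genes were at -0.21, with Atp2a2 at -1.05, Jph2 at -0.83, Gja1 at -0.79 and Kcnj2 at -0.73. Oxidative phosphorylation genes were at -0.18 and glycolysis genes at -0.16, with Cox8b at -1.36 and Hk2 at -1.80. Cell cycle genes were at -0.20, with 12 above and 26 below siUbe2v1 and only higher members, 2, past 1.5-fold, and immediate early genes at -0.19, with Fosb at -1.66 and Nr4a1 at -1.24.

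Cholesterol synthesis genes stood higher with AdUbe2v1 than with siUbe2v1, with a median of 0.39 (random range -0.04 to 0.13) and 21 of 22 above it; Dhcr7 was at 0.66, Hmgcs1 at 0.61 and Mvk at 0.60. The 26S proteasome list had a small median of 0.14 (random range -0.05 to 0.09), with all 31 subunits above siUbe2v1 and the largest ratio, 0.30, at Psmd8. Autophagy and lysosome genes were also at 0.14, with the autophagy receptor Sqstm1 at 0.45, and NRF2 targets at 0.19, with Osgin1 at 0.61, although Hmox1 of that list was at -1.64. p53 targets were at 0.20, with Fas at 0.77 and Pmaip1 at 0.72, and interferon-stimulated genes at 0.22, with Oasl at 1.14 and Isg15 at 0.93. Macrophage markers were at 0.47, all 19 above siUbe2v1, with Lyz2 at 0.91 and Tyrobp at 0.85. Of the remaining lists, immunoproteasome genes were at -0.05, with 6 above and 6 below siUbe2v1 and RT1-A2 at -1.23, and fatty acid genes at -0.03. Fibroblast markers were at -0.07, with Fbln1 at -1.08, Col3a1 at -0.32 and Col1a1 at 0.00. Smooth muscle markers were at -0.12, with Acta2 at -0.47, Tagln at 0.27 and Rgs5 2-fold higher. Epicardial markers were at -0.08 and went both ways, with Krt19 at -1.14, Krt18 at 1.44 and Aldh1a2 at -0.08. Actc1 and Tnnt2 were at -0.59 and -0.04, Eng and Kdr at 0.08 and 0.64, Fcer1g at 0.45, and Tubb3 and Cnp at -0.12 and 0.57. With a mean of at least 5 FPKM, the NRF2 (0.14), interferon (0.17) and immunoproteasome (-0.05) lists were inside the random range. With no filter the immunoproteasome (-0.0013) and epicardial (-0.01) lists were inside it. Ribosomal protein genes were at 0.08, a direction that turned to -0.01 under either scaling. The 8 highest protein-coding genes were Intu (3.18), Rab3b (1.76), Mex3a (1.33), Fibin (1.20), Rgs5 (1.12), Gdf15 (30.6 to 66.8 FPKM), Fxyd5 (1.09) and Cd200 (1.03). With a pseudocount of 5, Rgs5, Fxyd5 and Cd200 were under 2-fold, at 0.80, 0.90 and 0.76, and under the scalings Cd200 was at 0.95 and 0.94 and, by the median ratio, Fxyd5 just under 2-fold. The 8 lowest were Ggt5 (-3.10), Flnc (209 to 41.1 FPKM, -2.32), Mest (-2.00), Otud1 (-1.88), Hk2 (34.6 to 9.25 FPKM, -1.80), Rrad (-1.69), Hmox1 (-1.64) and Lcn2 (-1.61). The median over all tested genes was 0.10 and fell to 0.02 or below under either scaling.

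Whether genes that differed with R120G also differed with the direction of Ube2v1 manipulation was asked with ratios that share no library, R120G over control and AdUbe2v1 over siUbe2v1. Across 11841 genes Pearson's r was -0.06, with a 95% bootstrap interval over genes of -0.20 to 0.07, and Spearman's rho was 0.04. Among 10867 protein-coding genes r was 0.03. Genes are not independent replicates, so the interval covers the choice of genes only.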

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

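The search for genes in opposite directions was fixed before the data were examined, and the tests of explanations for the other patterns were chosen after the results were seen. Each group is 1 pooled library, so the differences given here were not tested across samples. Intu moved in opposite directions from R120G with siUbe2v1 and AdUbe2v1, and the difference of the log2 ratios was 3.18. Opposite directions were also seen for 5S_rRNA, with a difference of 2.47, and for AABR07070185.1, with a difference of -2.47. The share of small noncoding RNA genes itself differed between libraries, from 1.52% in R120G to 9.34% in control. Simulated unchanged libraries gave 2.35 genes in opposite directions. With a pseudocount of 5 the siUbe2v1 ratio of Intu was -0.88, no longer 2-fold.

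Oxidative phosphorylation genes stood higher in the R120G library than in control and lower with siUbe2v1 and AdUbe2v1 than in R120G. Better recovery of short, abundant transcripts in the R120G library would move ribosomal protein genes by a like amount. Oxidative phosphorylation genes moved further: the difference of the list medians was 0.45 for R120G over control (95% bootstrap interval over genes 0.40 to 0.50), -0.13 with siUbe2v1 (-0.22 to -0.09) and -0.39 with AdUbe2v1 (-0.46 to -0.31). As far as ribosomal protein genes stand for recovery, that argues against it as the whole cause. The lists were not matched on transcript length, and ribosomal protein genes were themselves at -0.39 with siUbe2v1 over R120G. Genes are not independent replicates, so the intervals in this section cover the choice of genes only. A larger share of myocytes, with fewer of every other cell type, would lower macrophage and fibroblast markers alike. Fibroblast markers had a median of -0.23, but macrophage markers had 0.38, with 14 of 19 above control. Smooth muscle and pericyte markers had -0.57, with 15 of 17 below control. The macrophage minus fibroblast difference of 0.60 had an interval of -0.02 to 1.09, and macrophage markers minus all genes 0.33 (-0.02 to 0.56). Both intervals span both signs, so this cause stays open. The macrophage direction goes against it, and the fibroblast and smooth muscle directions go with it. Sarcomere genes, at 0.40, were inside the random range, with 20 above and 7 below control and 5 of them 2-fold higher. A peculiarity of the single R120G library stays open as well, because 1 of the 2 other infected libraries stood above the random range against control; the mutant protein and infection are untested explanations.

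Macrophage markers stood lower in both Ube2v1 libraries than in R120G. All 19 of 19 tested markers were lower in both, which restates the pattern and does not tell fewer macrophages from lower marker expression. A general fall of non-myocyte RNA would lower fibroblast markers alike. Macrophage minus fibroblast medians were instead -1.01 with AdUbe2v1 (interval -1.37 to -0.62) and -1.63 with siUbe2v1 (-2.04 to -1.28). Whether Ube2v1 had a part in it was not tested.

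Interferon-stimulated genes stood higher with both reagents, although these are meant to move Ube2v1 in opposite directions. Over the 4 ratios of these libraries to R120G and to control, between 75.7% and 97.3% of the list members were higher. This largely restates the pattern, and the second reagent and an effect of Ube2v1 in the same direction both ways would each give it. The infected R120G library stood below the uninfected control in this list, with a median of -0.25 and 31 of 37 members lower. The other infected libraries stood above control, with medians of 0.28 (siUbe2v1) and 0.47 (AdUbe2v1). Because R120G over control joins infection with the mutant protein, it does not decide what infection alone does to this list. Libraries with a control reagent were not used here, and the second reagent and Ube2v1 cannot be told apart.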

How the results depend on the processing

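No paired analysis was possible because each group has 1 pooled library, and for the same reason no replicate could be left out. The numbers of gene lists outside the random range were 14 (R120G over control), 12 (siUbe2v1 over R120G), 11 (AdUbe2v1 over R120G) and 20 (AdUbe2v1 over siUbe2v1). They stayed within 1.5 times of these values under every setting. Scaling moves a list and its random lists nearly alike, so it could hardly change them. With the control library in place of R120G, different comparisons, they were 15 (siUbe2v1) and 16 (AdUbe2v1). The correlation without shared libraries stayed between -0.08 and 0.03. Counts of genes at 2-fold depended on the pseudocount. With 0.1 they were 1013 (R120G over control), 713 (siUbe2v1 over R120G) and 727 (AdUbe2v1 over R120G). With 5 they were 285, 156 and 178, with 126 for AdUbe2v1 over siUbe2v1 and 3 genes in opposite directions. A mean of at least 5 FPKM, which tests fewer genes, gave 256 (siUbe2v1 over R120G), 262 (AdUbe2v1 over R120G) and 130 (AdUbe2v1 over siUbe2v1). At 1.5-fold, a looser rule, the counts were 2424, 1776, 1746 and 561, with 18 in opposite directions. Protein-coding genes only, chosen after seeing the data, gave 277 (AdUbe2v1 over R120G), 81 (AdUbe2v1 over siUbe2v1) and 1 in opposite directions. The median of ribosomal proteins for AdUbe2v1 over siUbe2v1 changed sign, to -0.0059 scaled to the same total and -0.011 scaled by the median ratio; both lower that comparison's values as a whole. Of 92 named ratios, 4 were no longer past 2-fold with a pseudocount of 5, 2 by the median ratio and 1 scaled to the same total, where 1 other passed it. Absolute depth is unknown, which limits what can be said of low genes.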

Other observations

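Set against the control library, the libraries with a Ube2v1 reagent differed from R120G in several groups, a comparison chosen after seeing the data. Oxidative phosphorylation genes had medians of 0.28 with siUbe2v1 and 0.10 with AdUbe2v1, the latter inside the random range, against 0.80 for R120G. Interferon-stimulated genes had medians of 0.28 and 0.47, and macrophage markers of -1.19 and -0.69. NF-kB and inflammatory genes were at -0.54 and -0.58, and at -0.56 for R120G. All of these are ratios to the same control library, so a value peculiar to that library would appear in each, and no agreement is read from them.

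Chd9, a chromatin remodeler, had values of 960 (control), 4.33 (R120G), 168 (siUbe2v1) and 289 (AdUbe2v1) FPKM, a spread that no other protein-coding gene named here approached. Whether these are failed or misassigned estimates was not tested, and its ratios are not read as changes of the gene. Cryab was at 1585 FPKM in R120G, and the values do not separate endogenous from transgene reads. For R120G over control the median ratio was -0.01 in the lowest of 20 expression bins and 0.34 in the highest, and the random lists were matched on these bins.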
